A study of Mus musculus with 8 samples.

How the data were processed

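RNA from mouse bone marrow cells was measured on 1-colour expression arrays, in which labelled RNA (Cy3) binds to short DNA probes and the brightness of each spot is read by a scanner. There were 4 groups of 2 samples, 8 arrays in all. Macrophages grown from bone marrow for 7 days with M-CSF (macrophage colony-stimulating factor) were left in control medium, or received interleukin-4 (IL-4) or lipopolysaccharide (LPS) for 24 hours. Colony cells came from bone marrow plated for 7 days on a layer of endothelial cells in a medium for blood stem cells. Per the labels the mice carried a DsRed transgene on the B6 background, and RNA was purified on columns and checked on a Bioanalyzer and a NanoDrop. The labels do not say whether the 2 samples of a group came from separate animals or cultures, nor where the endothelial cells came from or whether they were removed before extraction. Substrate and medium differ together between colony cells and macrophages.

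The scanner files hold spot signals in intensity units, which per the file headers were made by Agilent Feature Extraction 10.7.3.1: the signal used here was background-subtracted and detrended over the array but not scaled between arrays. The same files hold other columns, 0 or 1 per spot, in which per the file headers the scanner software marks spots well above background, saturated, uneven or outlying. A value table deposited with the series is on the log2 scale. Set against the scanner files, each of its columns equalled the log2 signal minus 1 constant per array (Pearson r across probes of at least 0.9999751), with column medians of 2.89 and 2.96 (control), 2.93 and 2.93 (IL-4), 2.87 and 2.53 (LPS), and 2.91 and 2.88 (colony cells). What that constant is, and the rule by which the authors kept 34119 of 55681 probes, are not given. Partek 6.4 and RMA are named in the submitters' processing notes without a role. All 8 arrays lay on 1 slide and were read in 1 scan, so slide and scan cannot differ between groups.

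From the scanner files, spots marked uneven or outlying were left out, the background-subtracted signal was put on the log2 scale, the 75th percentile of each array was subtracted, and spots of the same probe were averaged. A probe was kept where it was well above background on both arrays of at least 1 group, which left 39411 probes. Each gene was represented by its probe with the highest mean over the 8 arrays, giving 26504 genes, of which 37 lacked a value on at least 1 array. Probe names were brought up to date from a table of reference transcripts: 26762 probes by the transcript in the array file, 3819 by symbol and 639 by a unique synonym, while 24461 kept the name in the file, 16194 of them probes for long intergenic RNAs. Probe positions are those of the array files on build mm9. No annotation of that build was at hand, so exons and untranslated regions are not given. Probes of close paralogs (Chil3 and Chil4, Rnase2a and the Ear genes, Lyz1 and Lyz2, mast cell proteases, histocompatibility genes) can bind RNA of more than 1 gene.

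Groups were compared with limma 3.58.1 in R 4.3.3: 1 linear model over all 8 arrays with 4 group means, moderated variances without an intensity trend, 4.0 residual and 1.57 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and calls of at least 2-fold were counted beside it. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so every call rests on variances shared across genes and groups, and its p measures the spread between these samples only. The number of arrays limits the precision. Values after ± are standard errors of the log2 fold change with 2 arrays per group. Where no probe of a gene was well above background on either array of 1 of the groups compared, a fold is given only as a lower bound, and where this held for both groups no fold is given. For Bex1, Adam22 and Scn3a a bound is given where only the probe representing the gene was dim. The bound sets the mean of the other group against the mean, over the dim arrays, of the gene's signal or the lowest signal well above background on that array, whichever was higher.

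The 6 comparisons, 30 gene lists (16 of functions and 14 of cell type markers), a panel of 15 genes and a rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a symbol that were well above background in the higher group, up to 4 called members with the largest change from each list described (or the 2 with the largest change where none was called), and the panel Arg1, Retnla, Chil3, Mrc1, Cd163, Nos2, Il12b, Il6, Tnf, Il10, Vegfa, Mmp9, Tek, Csf1r and Adgre1. Cd163 did not pass the filter. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over 180 tests of 30 lists in 6 comparisons. Camera with a correlation estimated from each list, and fry, which asks whether the genes of a list move one way on balance without setting them against other genes, stand beside it. Members were counted as risen or fallen over all genes tested and again adjusted over the list alone. Lists of pan-leukocyte, Y chromosome, X inactivation and mesothelial genes were added after values had been seen. Overlaps with a shared control are given beside n1 × n2 / N and beside values from 100 simulated data sets of unchanged groups.

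The steps were tested on simulated data with the spread of these arrays, in which 67, 67 and 66 genes per comparison had been changed 2-fold, 4-fold and 8-fold. Of genes changed 2-fold, 52.2% (LPS), 50.7% (IL-4) and 59.7% (colony cells against control) were recovered, and of genes changed 8-fold 84.8%, 90.9% and 89.4%, with 13, 8 and 9 false calls among 26467 genes. These false calls stood beside 35, 53 and 56 genes recovered at 2-fold, 4-fold and 8-fold for LPS. The same counts were 34, 54 and 60 for IL-4 and 40, 55 and 59 for colony cells. A far smaller share of genes was changed here than was called in the data. There it was 19% (IL-4 against control) to 71% (colony cells against control) of genes tested. The adjusted p depends on that share, so the recovery and false calls need not carry over. The test for lists called the 1 list that had been shifted and 0 of the others. Genes were drawn independently in these data, so this does not show how correlation between genes affects the list calls. A correlation of effects set to 0.5 on the axis of IL-4 against LPS was returned as 0.44, and unrelated changes gave 0.03. Alternatives covered background correction (normexp with an offset of 50), scaling, the filter, the choice of probe, the variance model, the samples in the fit, the replicate number as a block, the deposited value table, the test for lists and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.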

Results

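Expression was measured on 8 arrays, 2 for each of 4 groups. Bone marrow macrophages were kept in control medium or given IL-4, the standard stimulus of alternative activation, or LPS, a bacterial product and the standard stimulus of classical activation, for 24 hours. Colony cells grew from bone marrow over 7 days on a layer of endothelial cells. Between 62.4% and 67.5% of spots were well above background on 7 arrays, and 72.2% on LPS replicate 2. That array also held 105 uneven spots, against 0 to 5 on the others, and its spike-in detection limit of 2.10 was out of the scanner software's range, against 1.02 to 1.47. The median signal per array was 28.1 to 55.1 intensity units, over a median local background of 17 to 21.

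Colony cells lay farthest from the other groups. Across genes, Pearson r between the 2 arrays of a group was 0.995 (control), 0.997 (IL-4), 0.986 (LPS) and 0.996 (colony cells). Between groups its mean was 0.986 for control and IL-4, 0.943 for control and LPS, and 0.852, 0.852 and 0.824 for colony cells with control, IL-4 and LPS. Genes are not independent replicates. The first principal component held 68.1% of the variance and parted colony cells from macrophages, the second (23.3%) parted LPS, and the third (3.94%) IL-4.

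**Figure D1:**
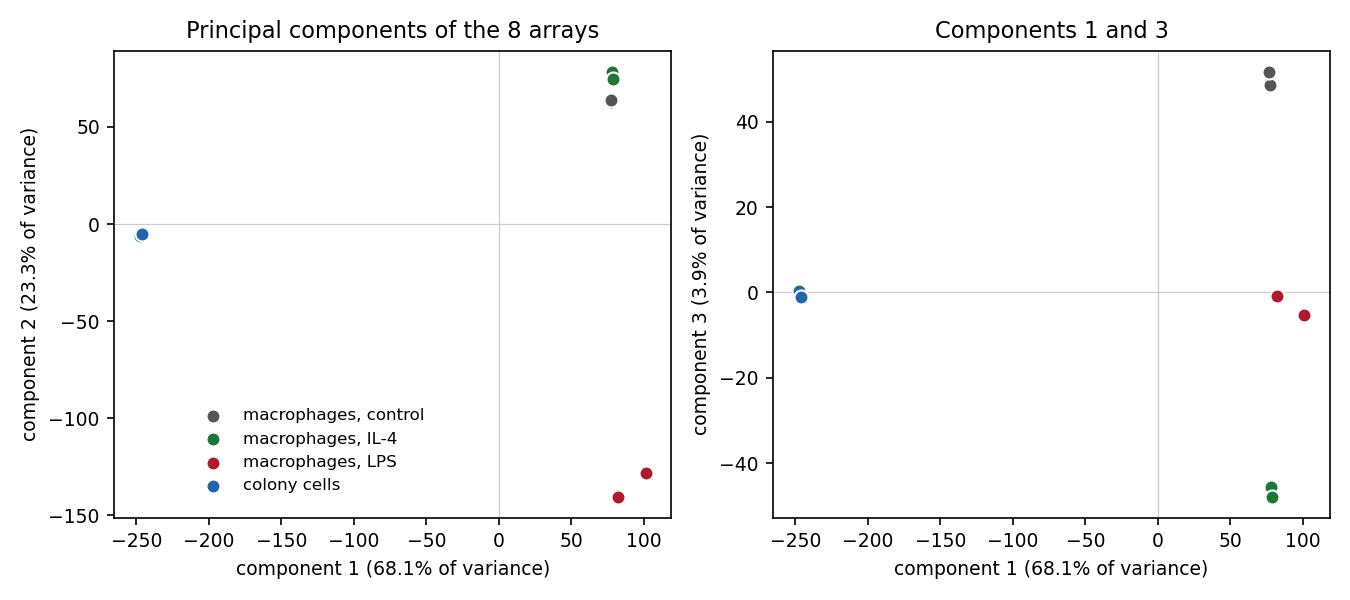
Principal components of the 8 arrays, from log2 signals of the genes tested, with 1 point per array coloured by group and components 1 and 3 at the right. The first component, with 68.1% of the variance, parts the colony cells from the 6 macrophage arrays, and the second, with 23.3%, parts the LPS arrays.

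Values below are log2 fold changes with standard errors, from 2 arrays per group. Genes are ranked by fitted change, and a gene dim in 1 group has a lower bound of its fold in place of that change. Such a bound holds for the background correction used here, carries no standard error, and can fail under another correction. For lists, the median log2 change is followed by the median relative to that of all genes, where the comparison shifted it. Counts adjusted over the list alone are given where they differ. With a preset correlation of 0.01 between genes, 80 of 180 list tests were called by camera, and with an estimated correlation 0 of 180. Each list's adjusted p comes first with the preset and then with the estimated correlation. By fry, the list moved one way on balance in 162 of 180 tests and changed in either direction in 178. Both arrays of one group lay outside both of the other for every called gene with complete values, which a call all but requires. Among all genes tested this held for 61.4% (IL-4 against control) to 89.5% (colony cells against IL-4), against 33.3% by chance.

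The comparison of LPS with control asked how these macrophages answer the classical stimulus. The highest fitted rises were those of cytokine and chemokine genes. They were Il6 (at least 1295-fold higher), which codes for interleukin-6, Cxcl3 (at least 1035-fold higher), a neutrophil-attracting chemokine, and Il1a (at least 1172-fold higher), which codes for interleukin-1 alpha. The acute-phase gene Saa3 (10.55 ± 0.21) came next, and the bounds of the genes named before it do not place them above it. Tarm1 (at least 309.6-fold higher), Shisa3 (at least 230.5-fold higher), Serpinb2 (at least 226-fold higher) and Slfn4 (9.67 ± 0.27) followed. The largest falls were those of the receptor gene Gpr34 (at least 269-fold lower), the anion transporter gene Slco2b1 (at least 197-fold lower), Bex1 (at least 131-fold lower), and Hpgd (-8.62 ± 0.16), whose enzyme breaks down prostaglandins. Rtn4rl1 (at least 48.0-fold lower), Samd4 (at least 44.5-fold lower), Adam22 (at least 35.9-fold lower) and the lectin gene Clec10a (-7.32 ± 0.09) came behind them. The highest adjusted p of these 16 was 1.2e-05. In the panel, Nos2, which codes for inducible nitric oxide synthase, rose by 5.03 ± 0.10, Tnf by 4.82 ± 0.09, Il10 by 2.39 ± 0.15 and Mmp9, measured on 1 of 2 control arrays, by 2.56 ± 0.18, and Il12b (by at least 6.74) and Arg1 (at least 159.8-fold higher) rose from below background. The mannose receptor gene Mrc1 (-5.56 ± 0.10) and the growth factor gene Vegfa (-2.62 ± 0.06) fell. Adgre1 lay higher than in control, and Csf1r and Chil3 lower, each by less than these panel genes.

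Among classical activation genes, 24 of 26 rose and 2 fell (median 6.16, 6.09 relative to all genes, 5.41 with bounds, adjusted p = 9.5e-13, estimated adjusted p = 0.21), with Il6, Cxcl3, Il1a and Saa3 ahead. Of interferon response genes, 28 of 29 rose and 1 fell (median 3.42, 3.34 relative to all genes, adjusted p = 2.7e-14, estimated adjusted p = 0.16). They included Oasl1 (5.46 ± 0.09) and Ifi44 (5.38 ± 0.11) and the chemokine genes Cxcl10 (5.17 ± 0.12) and Cxcl9 (5.11 ± 0.22). For NF-kB targets, 17 of 18 rose and 0 fell, or 18 and 0 adjusted over the list alone (median 2.08, 2.00 relative to all genes, adjusted p = 2.4e-08, estimated adjusted p = 0.12). Examples were Traf1 (5.96 ± 0.11) and the mitochondrial superoxide dismutase gene Sod2 (3.48 ± 0.12). In cholesterol synthesis, 18 of 22 rose and 1 fell (median 0.96, 0.89 relative to all genes, adjusted p = 1.4e-04, estimated adjusted p = 0.21), among them Hsd17b7 (2.50 ± 0.09) and Mvd (1.67 ± 0.10). Of glycolysis and hypoxia genes, 17 of 21 rose and 2 fell (median 1.20, 1.12 relative to all genes, adjusted p = 1.1e-04, estimated adjusted p = 0.34). The regulator gene Pfkfb3 (3.27 ± 0.08) rose and Ndrg1 (-3.41 ± 0.07) fell. Of complement genes, 9 of 12 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 1.52, 1.45 relative to all genes, adjusted p = 0.0017, estimated adjusted p = 0.21). Cfb (9.51 ± 0.10), which codes for factor B of the alternative pathway, rose.

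Of cell cycle genes, 6 of 32 rose and 22 fell (median -0.56, -0.63 relative to all genes, adjusted p = 0.0012, estimated adjusted p = 0.21), for example Cenpa (-4.71 ± 0.12) and Rrm2 (-2.69 ± 0.12). In the scavenger and tissue macrophage list, 4 of 21 rose and 13 fell (median -0.88, -0.96 relative to all genes, adjusted p = 0.0065, estimated adjusted p = 0.3). The scavenger receptor gene Marco (7.02 ± 0.08) rose, and the iron exporter gene Slc40a1 (-4.67 ± 0.22) and Gas6 (-4.15 ± 0.08) fell. Of fatty acid oxidation genes, 2 of 16 rose and 10 fell (median -0.62, -0.70 relative to all genes, adjusted p = 0.0091, estimated adjusted p = 0.38), Hadh (-1.44 ± 0.08) among them. Of lysosome genes, 5 of 23 rose and 14 fell (median -0.54, -0.61 relative to all genes, adjusted p = 0.014, estimated adjusted p = 0.4), with the lipase gene Lipa (-2.66 ± 0.15). With normexp background correction neither of these lists was called. Of alternative activation genes, 11 of 22 rose and 7 fell (median 0.76, 0.68 relative to all genes, 0.48 with bounds, adjusted p = 0.79, estimated adjusted p = 0.91). Arg1 rose, and Clec10a, Atp6v0d2 (-7.25 ± 0.09) and Mrc1 fell.

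Of 26504 genes, 14492 were called, 7660 higher and 6832 lower, and relative to the all-gene median of 0.07, 2955 were higher and 2965 lower by at least 2-fold. The higher share of 52.9% moved with the scaling: 42.5% with normexp, 44.2% with quantile normalization, 44.1% with both, 39.9% with median centring and 38.3% from the deposited table. Without LPS replicate 2, 13127 genes were called (6594 higher, 6533 lower), the lone array left being assumed to vary like the other groups. The gene Retnla was at least 1.44-fold higher (adjusted p = 0.011) but at -0.10 and not called with normexp. It was well above background on 1 of 2 LPS arrays, replicate 2, and without that array it was dim in both groups, which leaves no fold.

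Macrophages given IL-4 were compared with control to describe the alternative stimulus. Retnla, which codes for a secreted protein typical of alternative activation, was at least 40060-fold higher, and Arg1 (at least 448-fold higher), the gene of arginase 1, came next. The ribonuclease genes Rnase2a (9.06 ± 0.09) and Ear10 (7.55 ± 0.07), the sodium channel gene Scn3a (at least 186-fold higher), Apol7c (at least 63.3-fold higher), Tmem26 (at least 116-fold higher) and the retinol carrier gene Rbp4 (at least 45.5-fold higher) completed the 8 largest fitted rises. By their bounds alone, Apol7c and Rbp4 would not rank above Flt1, given below. The largest fitted falls were those of the fractalkine receptor gene Cx3cr1 (-5.33 ± 0.10), the interferon-induced genes Ifit3b (-4.64 ± 0.08), Ifit3 (-3.94 ± 0.08) and Ifit1bl1 (-3.84 ± 0.06), the formyl peptide receptor gene Fpr2 (-4.34 ± 0.10), the chemokine genes Cxcl10 (-4.23 ± 0.12) and Cxcl1 (at least 3.66-fold lower), and Adgre4 (-3.75 ± 0.16). By its bound alone, Cxcl1 would not rank above Oasl1 or Ifit1, given below. In the panel Chil3 rose by 3.93 ± 0.08 and Mrc1 by 0.84 ± 0.10, and Tnf (-0.78 ± 0.09), Il10 (-0.91 ± 0.15), Vegfa (-0.71 ± 0.06) and Adgre1 (-0.52 ± 0.09) fell. Nos2 (-0.13 ± 0.10, adjusted p = 0.44) and Csf1r (-0.32 ± 0.10, adjusted p = 0.084) did not pass the test.

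In the alternative activation list, 20 of 22 rose and 1 fell (median 3.68, 3.48 with bounds, adjusted p = 1.1e-19, estimated adjusted p = 0.12). Retnla, Arg1, Tmem26 and the VEGF receptor gene Flt1 (6.80 ± 0.23) were ahead. Of MHC class II genes, 8 of 12 rose and 1 fell, or 8 and 2 adjusted over the list alone (median 1.41, adjusted p = 3.4e-04, estimated adjusted p = 0.24). They included the class II transactivator gene Ciita (2.23 ± 0.46) and H2-DMa (2.21 ± 0.07). In cholesterol synthesis, 14 of 22 rose and 0 fell, or 17 and 0 adjusted over the list alone (median 0.52, adjusted p = 2.2e-09, estimated adjusted p = 0.12), with Cyp51 (1.19 ± 0.08) and Sqle (1.05 ± 0.09). Of osteoclast genes, 6 of 10 rose and 2 fell (median 1.39, adjusted p = 0.0011, estimated adjusted p = 0.21). The cell fusion genes Dcstamp (4.36 ± 0.10) and Ocstamp (3.93 ± 0.11) rose. Of fatty acid oxidation genes, 3 of 16 rose and 0 fell, or 5 and 0 adjusted over the list alone (median 0.22, adjusted p = 0.0012, estimated adjusted p = 0.32), and the regulator gene Ppargc1b was 8.55-fold higher.

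Of interferon response genes, 1 of 29 rose and 26 fell, or 1 and 27 adjusted over the list alone (median -1.40, adjusted p = 1.8e-21, estimated adjusted p = 0.12). Oasl1 (-3.50 ± 0.09) and Ifit1 (-3.00 ± 0.14) fell beside Cxcl10 and Ifit3. In the classical activation list, 4 of 26 rose and 14 fell (median -0.76, adjusted p = 3.0e-04, estimated adjusted p = 0.34). The interleukin-1 beta gene Il1b (-2.97 ± 0.18) fell and the endothelin gene Edn1 (at least 6.24-fold higher) rose. Of scavenger and tissue macrophage genes, 2 of 21 rose and 13 fell, or 3 and 14 adjusted over the list alone (median -0.40, adjusted p = 8.0e-05, estimated adjusted p = 0.21), including Marco (-1.60 ± 0.08) and Stab1 (-1.45 ± 0.08). Of macrophage genes, 2 of 19 rose and 9 fell, or 3 and 10 adjusted over the list alone (median -0.32, adjusted p = 0.0027, estimated adjusted p = 0.34), including Cx3cr1 and the LPS co-receptor gene Cd14 (-2.27 ± 0.13). Of monocyte genes, 1 of 12 rose and 5 fell, or 1 and 6 adjusted over the list alone (median -0.45, adjusted p = 0.0065, estimated adjusted p = 0.23), including Ly6c1 (-2.26 ± 0.07).

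Of 26504 genes, 5049 were called, 2616 higher and 2433 lower, and relative to the median of -0.01, 582 were higher and 576 lower by at least 2-fold. The count depended on single arrays. It was 2004 without IL-4 replicate 2, 2169 without IL-4 replicate 1 and 3086 without control replicate 2 (2 arrays against 1, the lone one taken to vary like the others). It was 2667 with median centring and 2833 from the deposited table.

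Colony cells were compared with control macrophages to ask what bone marrow cells on an endothelial layer express, with substrate and medium differing together. The gene Msln (mesothelin, a surface protein of mesothelium) was at least 12559-fold higher in colony cells, and Arg1 (at least 10152-fold higher), the arginase 1 gene, was next. Vat1l (at least 6052-fold higher), the matrix proteoglycan gene Dcn (at least 8915-fold higher), the homeobox gene Rhox5 (at least 8926-fold higher), the matrix gene Efemp1 (at least 3328-fold higher), the complement protease gene C1s2 (at least 2906-fold higher) and the uroplakin gene Upk3b (at least 2628-fold higher) followed. The largest falls were in Hpgd (at least 1087-fold lower), the potassium channel gene Kcnj10 (at least 197-fold lower), the membrane protein genes Ms4a4a (-9.15 ± 0.12) and Ms4a6b (at least 131-fold lower) and Calhm6 (at least 186-fold lower). Adgre4 (at least 121-fold lower), the lectin gene Clec4a1 (-8.93 ± 0.11) and Spic (at least 226-fold lower), which codes for a transcription factor of red pulp macrophages, came behind them. Among these 16 the highest adjusted p was 1.3e-04. In the panel, Mmp9, a matrix metalloproteinase gene measured on 1 of 2 control arrays, rose by 5.60 ± 0.18, Chil3 by 1.40 ± 0.08, Nos2 by 1.29 ± 0.10 and Vegfa by 0.82 ± 0.06, and Il6 (at least 13.8-fold higher) rose as well. The macrophage genes Csf1r (-3.73 ± 0.10), which codes for the M-CSF receptor, Adgre1 (-4.41 ± 0.09), which codes for F4/80, and Mrc1 (-2.14 ± 0.10) fell, as did Tnf (-3.62 ± 0.09) and Il10 (at least 18.0-fold lower). Retnla (at least 1.61-fold higher, adjusted p = 0.0061) was at -0.29 and Tek (at least 4.07-fold higher, adjusted p = 0.0036) at 0.15 with normexp, neither called.

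**Figure D2:**
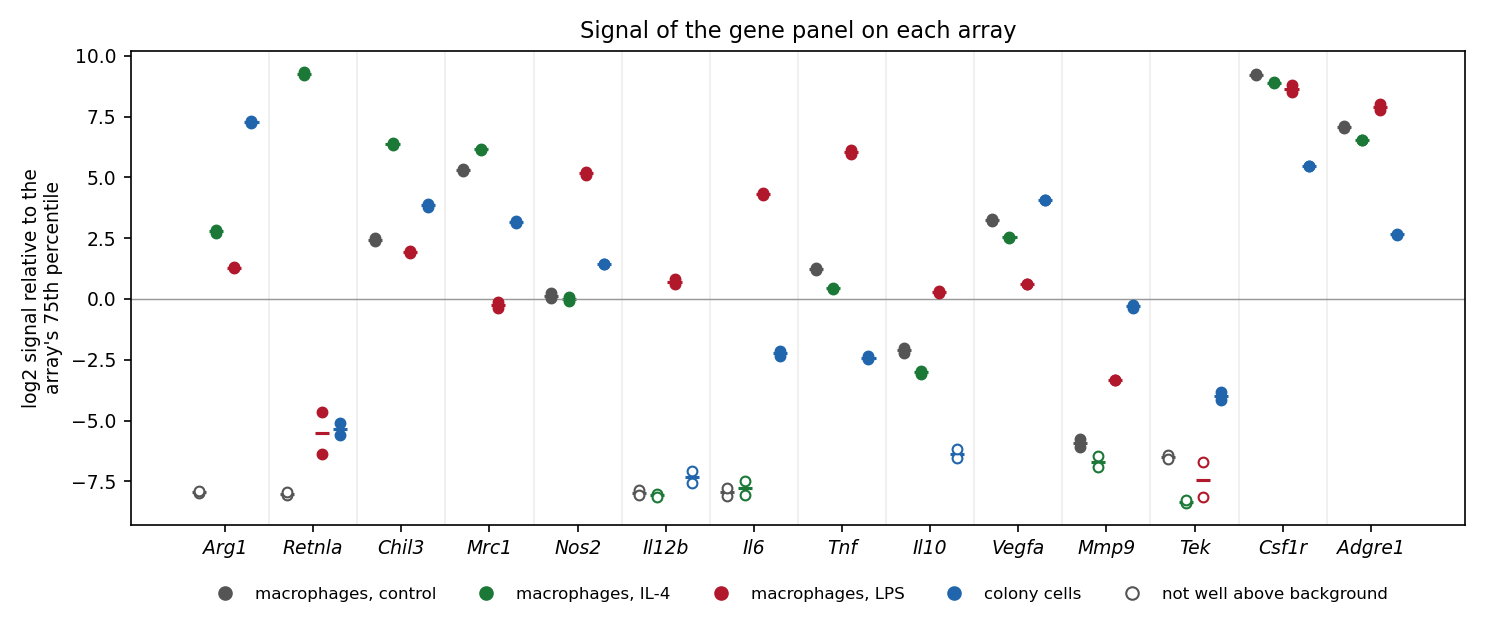
Log2 signal, relative to the 75th percentile of each array, of the panel genes on each of the 8 arrays, with 1 point per array, a line at each group mean, and open points where a group was not well above background. In colony cells Csf1r (-3.73 against control), Adgre1 (-4.41) and Mrc1 (-2.14) lie below the control arrays and Mmp9 (5.60) above them.

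Transcripts of leukocytes as a class were lower in the colony cell arrays. In a list of pan-leukocyte genes written after values had been seen, 22 of 23 fell and Srgn rose, with a median of -3.09, or 11.8% of control. The Y chromosome genes, also chosen after values had been seen, fell with a median of -2.90 (4 of 4, 2 of them well above background in colony cells), with Ddx3y at -2.97 ± 0.07 and Eif2s3y at -2.82 ± 0.09, and Xist, the RNA of X inactivation in female cells, was at least 116-fold higher and well above background only in colony cells. With normexp the pan-leukocyte and Y medians were -2.98 and -1.98. These values stand beside every group described for colony cells.

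Of macrophage genes, 1 of 19 rose and 18 fell (median -3.15, -2.80 relative to all genes, adjusted p = 1.4e-05, estimated adjusted p = 0.24), such as the lysozyme gene Lyz2 (-4.72 ± 0.09) and Mpeg1 (-4.08 ± 0.11). Of toll-like receptor genes, 0 of 15 rose and 15 fell (median -2.13, -1.78 relative to all genes, adjusted p = 1.8e-04, estimated adjusted p = 0.3), among them Tlr8 (-5.25 ± 0.16) and Tlr1 (-4.64 ± 0.06). Of lysosome genes, 2 of 23 rose and 21 fell (median -1.65, -1.30 relative to all genes, adjusted p = 1.8e-04, estimated adjusted p = 0.29), Lipa (-3.99 ± 0.15) among them. Of interferon response genes, 2 of 29 rose and 26 fell (median -1.60, -1.24 relative to all genes, adjusted p = 2.6e-05, estimated adjusted p = 0.26), with Mx1 (-5.57 ± 0.14) and Cxcl10 (-5.24 ± 0.12). Of MHC class II genes, 1 of 12 rose and 11 fell (median -2.07, -1.72 relative to all genes, adjusted p = 0.0042, estimated adjusted p = 0.3), with H2-Aa (-6.01 ± 0.11) and Cd74 (-4.66 ± 0.11). Of NF-kB targets, 1 of 18 rose and 15 fell (median -1.93, -1.58 relative to all genes, adjusted p = 0.0026, estimated adjusted p = 0.21), with Tnip3 (-4.15 ± 0.10). Of cholesterol efflux genes, 2 of 12 rose and 10 fell (median -3.21, -2.85 relative to all genes, adjusted p = 0.028, estimated adjusted p = 0.34). The LXR alpha gene Nr1h3 (-5.28 ± 0.08) fell and the desaturase gene Scd1 (at least 169-fold higher) rose. That list was not called with normexp or without either LPS array. In the scavenger and tissue macrophage list, 6 of 21 rose and 14 fell (median -2.04, -1.69 relative to all genes, adjusted p = 0.097, estimated adjusted p = 0.46). The fatty acid receptor gene Cd36 (-6.82 ± 0.16) fell and Lyve1 (at least 6.80-fold higher) rose.

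Of cell cycle genes, 29 of 32 rose and 2 fell (median 2.93, 3.29 relative to all genes, 2.74 with bounds, adjusted p = 5.1e-14, estimated adjusted p = 0.12), with Rrm2 (4.49 ± 0.12), Mcm2 (3.89 ± 0.09) and Ccnb2 (3.85 ± 0.10). Of glycolysis and hypoxia genes, 18 of 21 rose and 0 fell (median 0.80, 1.16 relative to all genes, adjusted p = 6.0e-07, estimated adjusted p = 0.29). They included the oxygen sensor gene Egln3 (6.96 ± 0.09) and the glucose transporter gene Slc2a1 (2.70 ± 0.11). In the angiogenesis list, 16 of 26 rose and 7 fell (median 1.13, 1.48 relative to all genes, 0.86 with bounds, adjusted p = 0.0049, estimated adjusted p = 0.27). The metalloproteinase gene Mmp2 (7.98 ± 0.27), the chemokine gene Cxcl12 (7.03 ± 1.10) and the adrenomedullin gene Adm (5.54 ± 0.16) rose. In cholesterol synthesis, 10 of 22 rose and 3 fell (median 0.17, 0.52 relative to all genes, adjusted p = 0.02, estimated adjusted p = 0.29). Fdft1 (1.93 ± 0.09) rose, the regulator gene Srebf2 (-3.42 ± 0.10) fell, and the list was not called with median centring or from the deposited table.

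Of alternative activation genes, 10 of 22 rose and 8 fell (median 0.18, 0.53 relative to all genes, adjusted p = 0.23, estimated adjusted p = 0.6). Arg1, the cadherin gene Cdh1 (at least 42.6-fold higher) and Klf4 (4.85 ± 0.11) rose and the nuclear receptor gene Pparg (-4.61 ± 0.10) fell. Among classical activation genes, 14 of 26 rose and 10 fell (median 0.50, 0.86 relative to all genes, adjusted p = 0.14, estimated adjusted p = 0.61). Cxcl3 (at least 68.5-fold higher) and Edn1 (at least 45.6-fold higher) and the prostaglandin synthase gene Ptgs2 (6.90 ± 0.12) rose. Above the pan-leukocyte median lay 19 of 22 alternative activation genes, 23 of 26 angiogenesis genes, 22 of 26 classical activation genes and 9 of 19 macrophage genes. The same held for 22 of 23 lysosome genes, 21 of 29 interferon response genes, 13 of 21 scavenger and tissue macrophage genes, 8 of 12 MHC class II genes and 8 of 15 toll-like receptor genes. Most genes on the arrays lay above it too, since only 2134 of 26504 were called at least 4-fold lower. A high count therefore does not set a list apart. Relative to the pan-leukocyte median, Mrc1 was at 0.95, Csf1r at -0.65 and Adgre1 at -1.32.

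Of fibroblast and stroma genes, 14 of 16 rose and 1 fell (median 5.48, 5.83 relative to all genes, adjusted p = 2.2e-08, estimated adjusted p = 0.21). Dcn and the collagen genes Col3a1 (11.20 ± 0.27), Col5a1 (at least 592-fold higher) and Col1a1 (9.06 ± 0.21) rose. Of mast cell and basophil genes, 9 of 9 rose and 0 fell (median 4.32, 4.68 relative to all genes, 2.42 with bounds, adjusted p = 1.5e-04, estimated adjusted p = 0.16), with the carboxypeptidase gene Cpa3 (at least 221-fold higher). Of the 12 in this list, Mcpt1, Mcpt2 and Tpsab1 did not pass the filter. The probes of Cpa3, Cma1, Fcer1a and Mcpt8 passed it only through the colony cell arrays. Being tested all but required these genes to be high there, so the count of risen members is not a free result. Of stem and progenitor genes, 8 of 14 rose and 1 fell (median 1.41, 1.76 relative to all genes, adjusted p = 0.0016, estimated adjusted p = 0.21), with Cd34 (6.76 ± 0.21) and Gata2 (at least 25.6-fold higher). Of neutrophil genes, 7 of 17 rose and 3 fell (median 0.92, 1.27 relative to all genes, adjusted p = 0.016, estimated adjusted p = 0.23). The granule protein genes Ctsg (2.91 ± 0.17) and Mpo (2.17 ± 0.10) rose. Of endothelial genes, 8 of 17 rose and 6 fell (median 1.21, 1.57 relative to all genes, 0.39 with bounds, adjusted p = 0.35, estimated adjusted p = 0.56). Esam (at least 455-fold higher) and Ptprb (at least 9.80-fold higher) rose and Vwf (-4.31 ± 0.09), the gene of von Willebrand factor, fell. Of the endothelial list, 5 of 22 markers (Tie1, Emcn, Sox17, Sox18 and Erg) did not pass the filter. The endothelial genes Ptprb, Mmrn1, Mmrn2 and Tek and the progenitor gene Gata2 passed it only through the colony cell arrays.

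**Figure D3:**
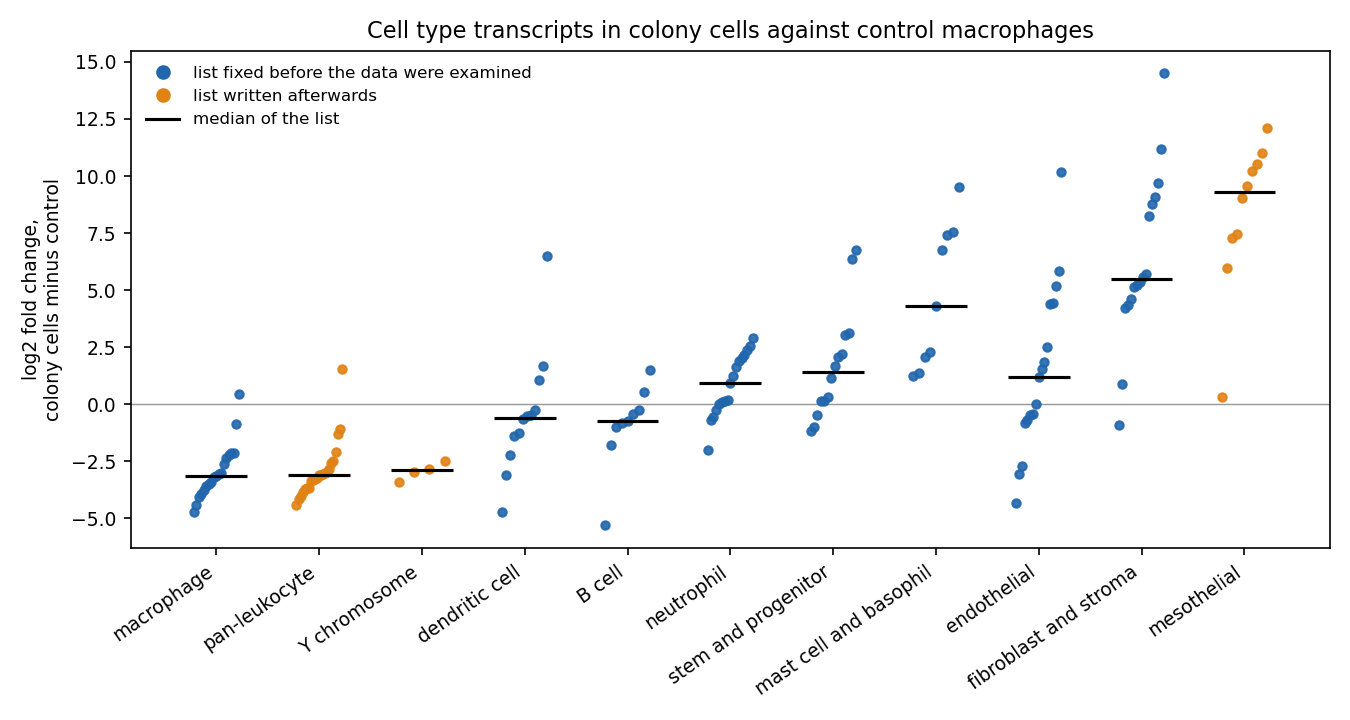
Log2 change in colony cells against control for members of the cell type lists, with 1 point per gene, a bar at each list's median, and lists written after values had been seen in orange. Fitted changes are drawn for dim genes as well. The fibroblast and stroma list has its median at 5.48 and the macrophage list at -3.15.

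Of 26504 genes, 18927 were called, 6551 higher and 12376 lower. The all-gene median was -0.35, between -0.14 and -0.50 over 6 scalings, and relative to it 5217 genes were higher and 3932 lower by at least 2-fold. The higher share of 34.6% lay between 26.9% (normexp) and 40.0% (normexp with quantile normalization) over 6 scalings, and with the latter 3514 were higher and 3384 lower by 2-fold before that median was taken off, against 4327 and 5793.

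Against IL-4 macrophages, colony cells were compared with the alternative reference. Retnla had the largest fall (-14.61 ± 0.54), and Arg1 was higher by 4.50 ± 0.07. The other large falls were Scn3a (at least 228-fold lower), Ms4a4a (-9.70 ± 0.12), Hpgd (at least 206-fold lower), Tmem26 (at least 149.9-fold lower), Clec4a3 (-8.95 ± 0.21), Gprc5c (-8.77 ± 1.28) and Clec4a1 (-8.64 ± 0.11). The largest rises were Msln (at least 13130-fold higher), Rhox5 (at least 9332-fold higher), Vat1l (at least 6327-fold higher), Dcn (at least 9320.1-fold higher), Efemp1 (at least 3479-fold higher), C1s2 (at least 3038-fold higher), Upk3b (at least 2747-fold higher) and C1s1 (at least 2956-fold higher). In the panel Mrc1 (-2.98 ± 0.10), Chil3 (-2.52 ± 0.08), Csf1r (-3.42 ± 0.10), Adgre1 (-3.89 ± 0.09), Tnf (-2.84 ± 0.09) and Il10 (at least 9.62-fold lower) fell, and Vegfa (1.54 ± 0.06), Nos2 (1.43 ± 0.10), Il6 (at least 14.4-fold higher), Mmp9 (at least 55.1-fold higher) and Tek (at least 4.25-fold higher) rose. Pan-leukocyte and Y chromosome medians were -2.97 and -2.89.

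In the alternative activation list, 4 of 22 rose and 17 fell (median -3.09, -2.72 relative to all genes, adjusted p = 0.0042, estimated adjusted p = 0.34). The ligand gene Pdcd1lg2 (-7.24 ± 0.14) and the transcription factor gene Irf4 (-6.19 ± 0.16) fell. Of MHC class II genes, 1 of 12 rose and 10 fell (median -3.88, -3.52 relative to all genes, -3.60 with bounds, adjusted p = 0.003, estimated adjusted p = 0.29), with Cd74 (-6.73 ± 0.11). Of osteoclast genes, 1 of 10 rose and 9 fell (median -2.10, -1.73 relative to all genes, adjusted p = 0.024, estimated adjusted p = 0.29), with Dcstamp (-8.46 ± 0.10). Of fatty acid oxidation genes, 1 of 16 rose and 14 fell (median -0.93, -0.57 relative to all genes, adjusted p = 0.0056, estimated adjusted p = 0.36), with Ppargc1b (-2.85 ± 0.09). That list was not called with quantile normalization. Among classical activation genes, 16 of 26 rose and 8 fell (median 1.55, 1.92 relative to all genes, adjusted p = 0.0027, estimated adjusted p = 0.4). Cxcl3 (at least 71.6-fold higher) and Il1a (at least 10.2-fold higher) rose. Of cell cycle genes, 29 of 32 rose and 2 fell (median 2.70, 3.07 relative to all genes, 2.64 with bounds, adjusted p = 4.6e-14, estimated adjusted p = 0.12). In the angiogenesis list, 16 of 26 rose and 8 fell (median 1.39, 1.76 relative to all genes, 1.08 with bounds, adjusted p = 0.0055, estimated adjusted p = 0.27). Of neutrophil genes, 12 of 17 rose and 2 fell (median 1.08, 1.45 relative to all genes, adjusted p = 3.0e-04, estimated adjusted p = 0.16), with Ly6g (5.04 ± 0.18), measured on 1 of 2 IL-4 arrays. Of fibroblast and stroma genes, 15 of 16 rose and 0 fell (median 5.42, 5.79 relative to all genes, adjusted p = 2.1e-09, estimated adjusted p = 0.21). Of immediate early and stress genes, 4 of 14 rose and 7 fell (median -0.30, 0.07 relative to all genes, adjusted p = 0.89, estimated adjusted p = 0.91), the test pointing up over a negative median. Trib3 (4.53 ± 0.11) rose and Atf3 (-4.28 ± 0.07) fell.

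Of 26504 genes, 18991 were called, 6441 higher and 12550 lower, and relative to the median of -0.37, 5170 were higher and 3800 lower by at least 2-fold. The higher share of 33.9% lay between 28.1% (median centring) and 40.2% (normexp with quantile normalization) over 6 scalings, and with the latter 3419 were higher and 3253 lower by 2-fold before the median was taken off, against 4232 and 5877.

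Colony cells were also set against LPS macrophages, the classical reference. The largest fall was in Il1b (-12.98 ± 0.18), which codes for interleukin-1 beta. It was followed by Slc13a3 (at least 1686-fold lower), Ms4a6b (at least 1137-fold lower), the formyl peptide receptor gene Fpr1 (-11.29 ± 0.18), Spic (at least 1046-fold lower), Ms4a4a (-11.06 ± 0.12), Gpr18 (at least 378-fold lower) and the itaconate enzyme gene Acod1 (-10.52 ± 0.11). The largest rises were Vat1l (at least 6528-fold higher), Msln (14.44 ± 0.91), Efemp1 (at least 3590.2-fold higher), Prss23 (at least 2893-fold higher), Rhox5 (13.36 ± 1.19), the transcription factor gene Wt1 (at least 2296-fold higher), Upk1b (at least 2378-fold higher) and Perp (at least 2259.9-fold higher). In the panel Tnf (-8.44 ± 0.09), Il6 (-6.55 ± 0.22), Il12b (at least 131-fold lower), Nos2 (-3.74 ± 0.10), Il10 (at least 94.3-fold lower), Csf1r (-3.17 ± 0.10) and Adgre1 (-5.24 ± 0.09) fell. In turn Arg1 (5.99 ± 0.07), Vegfa (3.44 ± 0.06), Mrc1 (3.42 ± 0.10), Mmp9 (3.04 ± 0.18), Chil3 (1.91 ± 0.08) and Tek (at least 4.39-fold higher) rose. Msln, Rhox5 and Retnla were well above background on 1 of 2 LPS arrays, replicate 2, and without replicate 1 Msln was at 12.96 and Rhox5 at 11.38. Retnla was at 0.16 ± 0.54 (adjusted p = 0.79), and at -0.70 without LPS replicate 1. The pan-leukocyte and Y medians were -3.37 and -2.50.

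Among classical activation genes, 0 of 26 rose and 26 fell (median -4.22, -3.81 relative to all genes, adjusted p = 3.0e-08, estimated adjusted p = 0.23), with Il1b and the chemokine gene Ccl5 (-9.61 ± 0.16). Of interferon response genes, 0 of 29 rose and 29 fell (median -4.84, -4.42 relative to all genes, adjusted p = 4.5e-10, estimated adjusted p = 0.21), with Cxcl10 (-10.41 ± 0.12). For NF-kB targets, 0 of 18 rose and 18 fell (median -3.39, -2.97 relative to all genes, adjusted p = 3.0e-06, estimated adjusted p = 0.16), with Traf1 (-8.23 ± 0.11). In the alternative activation list, 12 of 22 rose and 8 fell (median 0.84, 1.26 relative to all genes, adjusted p = 0.031, estimated adjusted p = 0.44). Cdh1 (6.30 ± 0.78) and Atp6v0d2 (5.53 ± 0.09) rose and Socs1 (-4.93 ± 0.12) fell. In the angiogenesis list, 14 of 26 rose and 8 fell (median 1.69, 2.11 relative to all genes, 1.38 with bounds, adjusted p = 0.013, estimated adjusted p = 0.3), with Cxcl12 (9.19 ± 1.10). Both genes were well above background on 1 of 2 LPS arrays, replicate 2, and without replicate 1 Cdh1 was at 5.01 and Cxcl12 at 7.37. Neither list was called with quantile normalization, alone or after normexp, nor was the first with the mean of a gene's probes or the second with probes well above background on all arrays. Of cell cycle genes, 30 of 32 rose and 1 fell (median 3.19, 3.61 relative to all genes, 3.11 with bounds, adjusted p = 3.4e-14, estimated adjusted p = 0.12), with Kif11 (5.16 ± 0.11), measured on 1 of 2 LPS arrays. Of glycolysis and hypoxia genes, 7 of 21 rose and 13 fell (median -0.40, 0.02 relative to all genes, adjusted p = 0.92, estimated adjusted p = 0.97). Their mean was 0.05 and the test pointed up. Ndrg1 (4.82 ± 0.07) rose and Pfkfb3 (-2.46 ± 0.08) fell.

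Of 26504 genes, 20283 were called, 7099 higher and 13184 lower, and relative to the median of -0.42, 5856 were higher and 4682 lower by at least 2-fold. The higher share lay between 32.6% (normexp) and 44.6% (normexp with quantile normalization) over 6 scalings, and with the latter 4151 were higher and 3651 lower by 2-fold before the median was taken off, against 4568 and 7371. Without LPS replicate 2, 19298 were called (7109 higher, 12189 lower).

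The stimuli were set against each other to give an axis of polarization. In IL-4 macrophages Retnla (14.77 ± 0.54), Bex1 (at least 747-fold higher), the proton pump gene Atp6v0d2 (9.87 ± 0.09), Scn3a (at least 201-fold higher), Rnase2a (9.21 ± 0.09), Slco2b1 (at least 126-fold higher), the transcription factor gene Irf4 (8.41 ± 0.16) and Hebp2 (at least 90.8-fold higher) were highest over LPS. Saa3 (-12.75 ± 0.21), Il1a (at least 1226-fold lower), Fpr1 (-12.24 ± 0.18), Slfn4 (at least 2323-fold lower), Il6 (at least 1354-fold lower), Cxcl3 (at least 1082-fold lower), Cfb (-11.54 ± 0.10) and Fpr2 (-11.40 ± 0.10) were lowest. Each of Retnla (replicate 2) and Irf4 (replicate 1) was well above background on 1 of 2 LPS arrays, and without replicate 1 Retnla was at 13.90. In the panel Mrc1 (84.5-fold), Chil3 (4.43 ± 0.08), Vegfa (1.91 ± 0.06) and Arg1 (1.49 ± 0.07) were higher. In turn Tnf (-5.60 ± 0.09), Nos2 (-5.16 ± 0.10), Il12b (at least 112-fold lower), Il10 (-3.29 ± 0.15), Mmp9 (at least 6.71-fold lower) and Adgre1 (-1.35 ± 0.09) were lower, and Csf1r (0.25 ± 0.10, adjusted p = 0.089) did not pass.

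In the alternative activation list, 17 of 22 rose and 3 fell, or 18 and 3 adjusted over the list alone (median 3.53, 3.59 relative to all genes, adjusted p = 6.3e-08, estimated adjusted p = 0.21), with Clec10a (7.88 ± 0.09). Among classical activation genes, 1 of 26 rose and 23 fell (median -7.06, -7.00 relative to all genes, -6.20 with bounds, adjusted p = 4.4e-14, estimated adjusted p = 0.21). Of interferon response genes, 0 of 29 rose and 28 fell (median -5.15, -5.09 relative to all genes, adjusted p = 7.1e-18, estimated adjusted p = 0.15), with Oasl1 (-8.96 ± 0.09). Of fatty acid oxidation genes, 13 of 16 rose and 0 fell (median 0.87, 0.94 relative to all genes, adjusted p = 4.7e-05, estimated adjusted p = 0.26), with Hadhb (1.54 ± 0.07). Of 26504 genes, 13948 were called, 6832 higher and 7116 lower, and relative to the median of -0.06, 2770 were higher and 2966 lower by at least 2-fold. The higher share of 49.0% was 57.2% with quantile normalization, 57.3% with normexp as well, 63.8% with median centring and 66.2% from the deposited table. Without LPS replicate 2, 12414 genes were called (6387 higher, 6027 lower).

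The colony cell change was then set against this axis of polarization. Genes at least 2-fold higher with IL-4 than with LPS (2547) rose 2-fold in colony cells against control in 21.4% and fell in 41.7%, and genes higher with LPS (3145) rose in 25.9% and fell in 30.9%. Of all 26504 genes, 4327 rose and 5793 fell 2-fold, so both sets exceeded the all-gene shares in both directions. The medians of the sets relative to all genes were -0.27 (higher with IL-4) and 0.02 (higher with LPS). Neither set passed the camera test, while by fry the set higher with IL-4 passed, downward. Across 26504 genes the IL-4 minus LPS change and the colony cell minus control change had a Pearson r of -0.11 and a Spearman rho of -0.09, and genes are not independent replicates. Among called genes 48.0% had the same sign (41.4% with median centring, 41.0% from the deposited table). The r was -0.04 with normexp, -0.06 without LPS replicate 2 and -0.15 without LPS replicate 1.

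**Figure D4:**
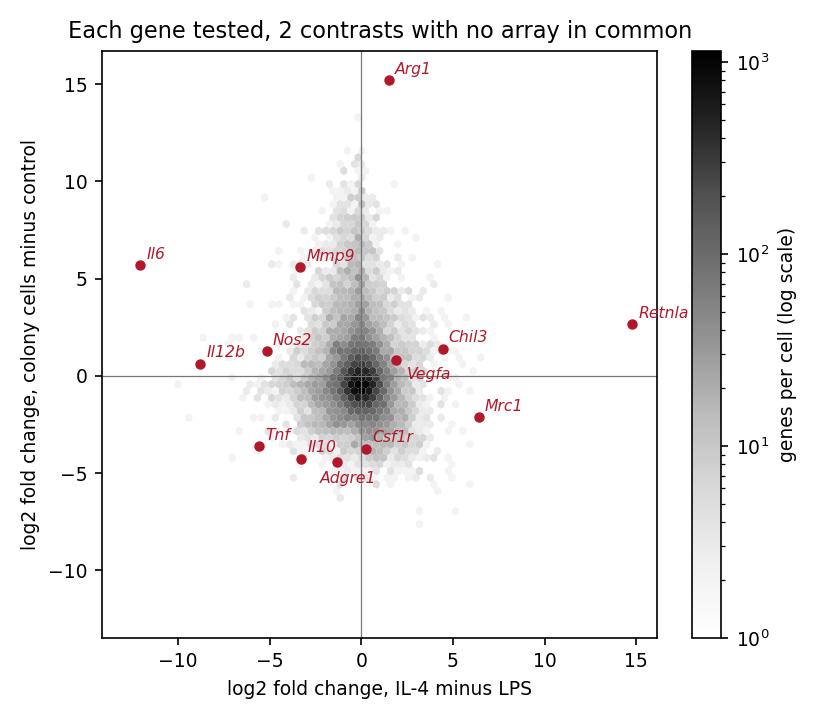
Change in colony cells against control over change in IL-4 against LPS, both in log2, with genes counted per cell in grey and panel genes in red. The cloud has a Pearson r of -0.11 across 26504 genes.

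Both references share the control arrays with the colony cell comparison. Of 575 genes at least 2-fold higher with IL-4, 252 rose and 138 fell 2-fold in colony cells, against 93.9 and 126 from the product of the counts over all genes, and of 590 lower ones 165 rose and 301 fell (96.3 and 129). Of 3191 genes higher with LPS 888 rose and 792 fell (521 and 697), and of 2699 lower ones 515 rose and 1208 fell (441 and 590). The covariance of the changes was 0.135 for IL-4 and 0.438 for LPS, against 0.040 for each in the simulations, while r was 0.11 and 0.17 against a simulated 0.50. The differences in covariance were 0.0953 and 0.398. In the simulations of unchanged groups the overlaps were 0 in each direction, which does not size the effect of shared controls among changed genes. A split would leave 1 control array per comparison, so the controls were not split. Shared controls move both changes the same way. Part of each excess in the same direction can therefore come from them, but not the excesses in opposite directions.

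**Figure D5:**
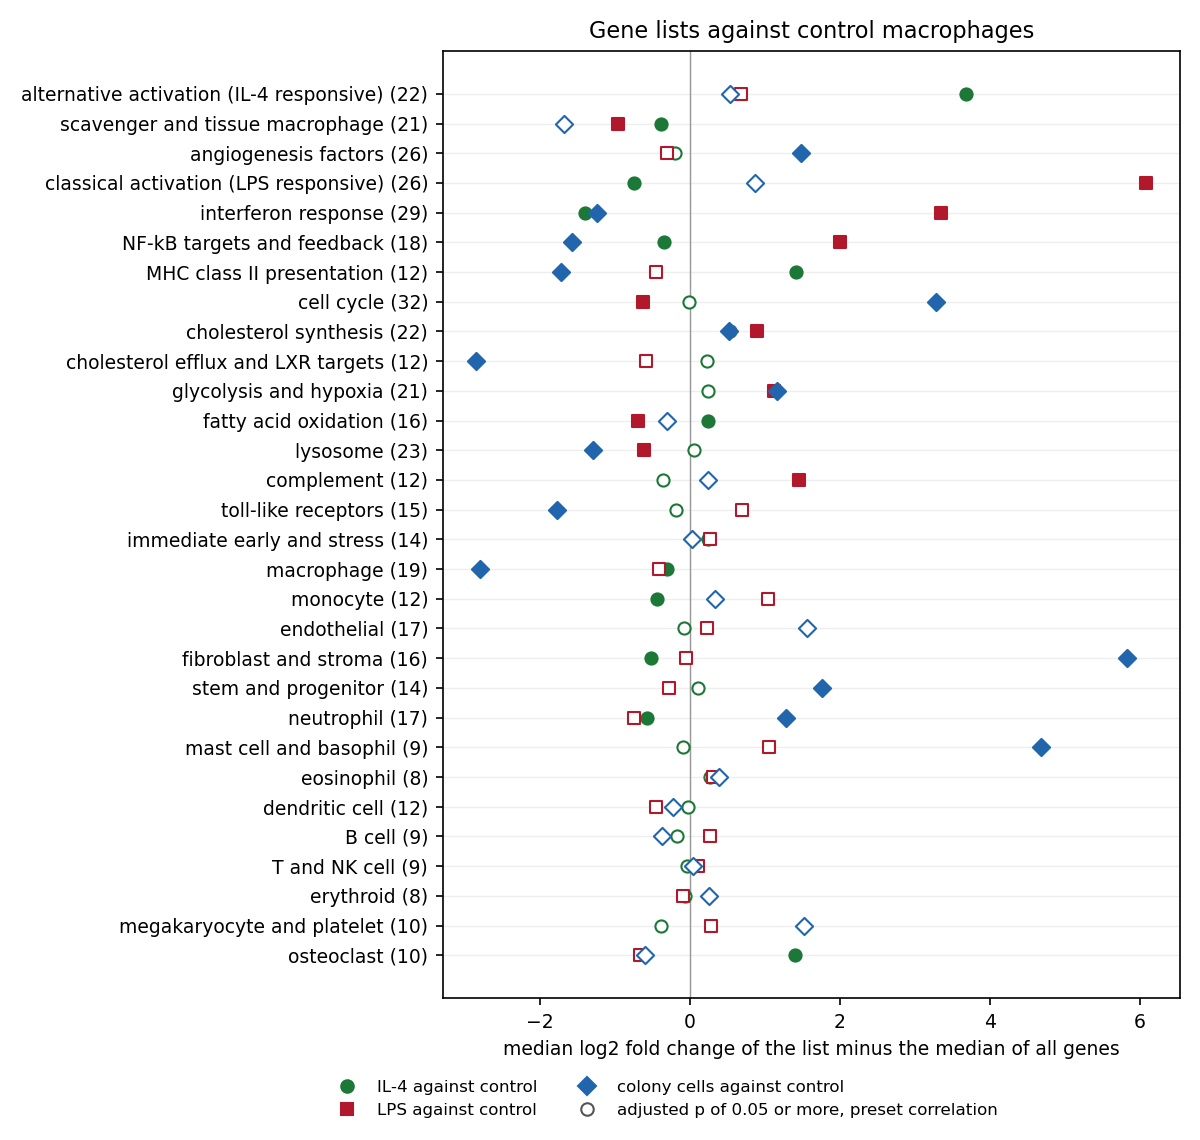
Median log2 change of each of 30 gene lists minus the median of all genes, against control, with tested genes in brackets and open symbols for lists not called. Classical activation lies at 6.09 with LPS and alternative activation at 3.69 with IL-4.

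On build mm9 the probes of these genes lay at chromosome 10, 24636194 to 24636253 (Arg1), chromosome 16, 48844447 to 48844506 (Retnla), chromosome 17, 25885569 to 25885628 (Msln), chromosome 10, 96980233 to 96980292 (Dcn), chromosome 18, 61290725 to 61290784 (Csf1r), chromosome 17, 57622868 to 57622927 (Adgre1), chromosome 2, 14253273 to 14253332 (Mrc1), chromosome 17, 46154387 to 46154446 (Vegfa), chromosome 2, 164780620 to 164780679 (Mmp9) and chromosome 5, 30346367 to 30346426 (Il6). Among 8103 genes with several probes, probes were called in both directions for 490 (LPS against control), 19 (IL-4 against control) and 499 (colony cells against control) genes. Of the collagen I genes, Col1a1 rose by 9.06 ± 0.21 in colony cells and Col1a2 fell by 0.90. Each value comes from the 1 probe that represented the gene, and the cause of the difference was not tested.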

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

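The polarization setting limited to genes well above background on all 6 macrophage arrays was chosen after seeing the data, and the other tests of this part were planned. Of 799 called results for named genes, 729 kept their direction and call under every alternative in which they were tested, leaving out each array included, and 17 changed sign in at least 1. A gene left untested by an alternative, such as a stricter filter, was judged on the remaining ones. With every probe on its own, the probe of the main fit was used. Of 80 list shifts called by camera with the preset correlation, 65 kept theirs under every alternative run with that test and 0 changed sign, while with an estimated correlation 0 of 180 were called. The cause was not tested for the changes below unless the alternative's construction gives it.

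With normexp background correction, which changes dim signals most, these changed sign: in LPS against control Prss34 (-0.055), Blk (-0.0072), Il2rb (-0.21) and Retnla (-0.10). In colony cells against control they were Eomes (-0.25), Retnla (-0.29) and Il12b (-0.56), against IL-4 Vpreb3 (-0.017), Eomes (-0.024) and Il12b (-0.30), and in IL-4 against LPS Cpa3 (0.074). Il12b and Cpa3 were dim in both groups of these comparisons, so theirs are differences between background signals and not folds. With the mean of a gene's probes Ermap was at 1.17 in LPS against control. Nkg7 was at 1.05, 1.12 and 1.25 in colony cells against control, IL-4 and LPS, and against LPS Zbtb46 was at 0.92 and Itgb3 at -0.35. Retnla in colony cells against LPS was at -0.70 without LPS replicate 1 and 1.03 without LPS replicate 2, when it was dim on the LPS array left, so the second value is no fold.

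Genes called in IL-4 against control numbered 2667 with median centring, 2833 from the deposited table and 3281 with only the compared groups in the fit, which leaves fewer arrays to estimate the spread. Leaving out 1 array gave 2004 (without IL-4 replicate 2) to 5270 (without LPS replicate 1 or 2). In the other comparisons the count stayed within 1.5 times under every setting, and leaving out an array gave 12617 to 14416 (LPS against control), 16464 to 19598, 16302 to 19582 and 17919 to 20134 (colony cells against control, IL-4 and LPS), and 10529 to 13938 (IL-4 against LPS). A lone array left in a group was assumed to vary like the other groups.

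The correlation on the polarization axis was -0.039 with normexp, -0.069 with quantile normalization, -0.060 with both, -0.090 with no filter, -0.071 with probes well above background on all arrays, -0.12 with every probe on its own and -0.060 over genes well above background on all 6 macrophage arrays. It ranged from -0.15 to -0.065 (without LPS replicate 1 and without LPS replicate 2) when 1 array was left out, and it was negative in each of these. Called list shifts numbered 0 with an estimated correlation and 162 with fry, against 80. The overlaps with colony cells, summed over IL-4 and LPS so that a gene in both counts for each, came to 2649 at 2-fold, against 8999 for all calls, since fewer genes enter, and genes lower in both stood at 2.33 (IL-4) and 2.05 (LPS) times the product of the counts.

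Otherwise normexp ended the call of 25 named results and 7 lists, quantile normalization that of 15 and 7, and the fit on only the compared groups that of 23 named results. Leaving out IL-4 replicate 1 or 2 ended 34 and 33 calls of genes and lists, and each other array 9 to 22. The replicate numbers did not pair the samples. With them as a block 13714, 3861, 18536, 18518, 19846 and 13162 genes were called (LPS and IL-4 against control, colony cells against control, IL-4 and LPS, IL-4 against LPS). A slide block could not be fitted, since there was 1 slide. Signal over background limits what dim genes show: a gene dim in 1 group gives only a lower bound, which depends on the background correction.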

Other observations

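In this part the tests of pan-leukocyte, Y chromosome, Xist and endothelial transcripts were chosen only after some of the result had been seen, and the mesothelial list was written after Msln, Upk3b, Upk1b and Wt1 had been seen. The marker lists of 7 further blood cell types were not called in colony cells against control. Absent from the array or stopped by the filter were 3 of 12 B cell, 5 of 14 T and NK cell, 4 of 12 erythroid, 2 of 14 dendritic cell and 1 of 13 monocyte genes. Of monocyte genes, 6 of 12 rose and 6 fell (median -0.02, 0.34 relative to all genes, adjusted p = 0.51, estimated adjusted p = 0.63), with Ly6c1 (1.64 ± 0.07) up and the chemokine receptor gene Ccr2 (-3.89 ± 0.10) down. Of eosinophil genes, 3 of 8 rose and 2 fell (median 0.03, 0.39 relative to all genes, adjusted p = 0.51, estimated adjusted p = 0.65), with the granule gene Prg2 (2.57 ± 0.15) up and the eotaxin receptor gene Ccr3 (-4.77 ± 0.14) down. Of dendritic cell genes, 3 of 12 rose and 7 fell, or 3 and 8 adjusted over the list alone (median -0.58, -0.22 relative to all genes, adjusted p = 0.58, estimated adjusted p = 0.72), with Dpp4 (at least 64.3-fold higher) up and Irf8 (-3.08 ± 0.07) down. Of B cell genes, 0 of 9 rose and 5 fell (median -0.73, -0.37 relative to all genes, adjusted p = 0.46, estimated adjusted p = 0.56), with the receptor chain gene Cd79b (-5.29 ± 0.11) down. Of T and NK cell genes, 4 of 9 rose and 5 fell (median -0.31, 0.04 relative to all genes, adjusted p = 0.86, estimated adjusted p = 0.89), with the granzyme gene Gzmb (at least 23.9-fold higher) up and Nkg7 (-2.11 ± 0.15) down, the latter up with the mean of its probes. Of erythroid genes, 1 of 8 rose and 3 fell (median -0.10, 0.25 relative to all genes, adjusted p = 0.95, estimated adjusted p = 0.97), with Gata1 (2.76 ± 0.36) up and Epor (-2.17 ± 0.12) down. Of megakaryocyte and platelet genes, 6 of 10 rose and 3 fell (median 1.16, 1.51 relative to all genes, adjusted p = 0.21, estimated adjusted p = 0.56), with the integrin gene Itga2b (2.94 ± 0.44) up.

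Complement genes also parted in colony cells: 5 of 12 rose and 6 fell (median -0.11, 0.25 relative to all genes, adjusted p = 0.43, estimated adjusted p = 0.58). C1s1 (at least 2827-fold higher), C2 (7.78 ± 0.10), C1ra (4.65 ± 0.10) and the inhibitor gene Serping1 (6.37 ± 0.14) rose. The receptor genes C3ar1 (-3.42 ± 0.12) and C5ar1 (-2.66 ± 0.08) and, in the scavenger and tissue macrophage list, C1qb (-3.73 ± 0.07) fell, named after their values were seen. The mean of this list was 2.02 over a negative median, and the test pointed up. The T and NK cell median was negative as well, with a mean of 0.54, and so were the monocyte and erythroid medians, with means of 0.11 and 0.15.

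In colony cells, macrophage transcripts fell and those of fibroblasts and stroma rose. The scaling of the arrays, by the rule set, would need the macrophage median to show a fall under 2-fold with some scaling. Its highest value over 6 scalings was -2.69. The all-gene median moved only between -0.14 and -0.50 over them, so they could hardly have met that rule. They show only that the list lay below the all-gene median under each. Female marrow pooled into the colony cells would on its own lower Y chromosome transcripts and raise Xist but leave pan-leukocyte genes in place. Of these, 95.7% fell 2-fold or more. That argues against female marrow as the only cause, and female marrow beside another change was not tested. RNA of female cells from outside the marrow may account for part of the pattern: the pan-leukocyte median differed from the Y chromosome median by -0.19, and Xist was well above background only in colony cells. With normexp the medians lay farther apart, at -2.98 and -1.98, and with quantile normalization as well at -2.81 and -1.83. A change of the marrow cells themselves on this substrate and in this medium stays open and was not tested, since the design joins it to the other differences of the colony cells.

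The transcripts that colony cells gained were set against markers of candidate sources. Endothelial cells with their usual transcripts would bring most endothelial markers: 16 of 22 were well above background in colony cells, and 8 of 22 were also 2-fold higher than in control. This stays open by a rule widened after the count of 8 had been seen. By it, markers well above background count whether or not they rose, since markers that control macrophages express have less room to rise. Vwf fell, and Tie1, Emcn, Sox17, Sox18 and Erg did not pass the filter. Pecam1, Egfl7, Cldn5 and Vwf were well above background on both control arrays too, so the count of 16 cannot tell endothelial cells from macrophages. Cells with mesothelial transcripts may be a source, since 9 of 11 mesothelial markers were well above background and 2-fold higher, among them Rspo1 (at least 1103-fold higher), Crb2 (at least 519.8-fold higher) and Pdpn (10.23 ± 0.23), and 3 of the 11 were also well above background in control. Pdpn also rose by 7.48 ± 0.23 in macrophages given LPS, so it does not by itself tell mesothelial cells from macrophages. Fibroblast and stroma markers passed in 14 of 16, so mesothelial cells and stroma were not separated by these lists, and the labels name no sort of the cells.

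LPS replicate 2 had 23.7% of the probes dim on the other 5 macrophage arrays well above background, against 0.800% to 4.57% for the same share of those arrays. If RNA of colony cells had caused this, probes bright in colony cells would have appeared over 1.5 times as often as dim ones, and the ratio was 1.01 (95% interval 0.932 to 1.10, a criterion added after the ratio was seen), against 1.53 to 3.21 on the other macrophage arrays. Those 5 arrays all passed the 1.5 mark at far lower shares, so the mark is not particular to RNA of colony cells. Uneven hybridisation would have concentrated the newly bright probes, and the highest of 16 strips had 1.20 times the share of the median strip. On the other macrophage arrays this ratio was 2.29 to 4.59. Their median strips held 0.735% to 3.74%, against 24.2% here, so the ratios are not alike. The strips were cut by spot number only, and unevenness in another direction was not tested. What raised the dim signals on this array stays open, and no biological explanation was tested.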
